A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

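RNA of wild-type BY4741 and of 11 strains, each lacking 1 ribosomal protein gene, was measured on 24 Affymetrix YG-S98 arrays, 2 biological replicates for each of the 12 strains. Per the labels, 50 mL cultures in YPD at 30 °C were taken in early log phase, RNA was extracted with hot phenol, and biotin-labelled cRNA was made from oligo-dT-primed cDNA. The deposited values are 1 intensity per probe set and array, on a linear scale. How probes were summarised to probe sets, and whether arrays were scaled to each other, is not given in the sources used here. Of 9335 deposited probe sets, 60 control probe sets were set aside and 9275 were tested, of which 6504 carry 1 gene name, 328 carry several and 2443 carry none. Names were brought to the current gene names of the yeast reference annotation, and positions on chromosomes were taken from the systematic names.

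Values under 3.6, the 10th percentile of all values, were raised to it (9.88% of values), and log2 values were quantile normalized between arrays. The background of an array was the 95th percentile of 19 control probe sets for sequences absent from yeast. Median signals of 36.3 to 61.4 stood against backgrounds of 5.55 to 30.8, the highest in rps0a replicate 2, and a probe set was taken as not above background in a strain when its signal exceeded the background in neither array. For groups of strains a bound or no fold is given where this held in at least 1 strain on the lower side, a rule chosen after seeing the data. Precision came from the spread between replicates, pooled over strains. Each deletion was compared with wild type, the 5 paralog pairs with each other, and the mean of the 11 deletions with wild type, in 1 limma fit of 12 group means (limma 3.58.1 in R 4.3.3, 12 residual degrees of freedom, data.table version 1.17.8), with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. A moderated F test asked for any difference among the 12 strains. For large against small subunit deletions the unit was the strain, 7 against 4, each as the mean of its 2 arrays. Remaining copies were also adjusted over the paralogs alone.

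Of the 37 gene lists, 35 with at least 5 measured genes were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated per list. The test used 5656 genes, each by the probe set with the highest mean (315 genes had several). Lists called in no deletion against wild type were the unfolded protein response, sulfur and methionine metabolism, zinc regulon, hexose transporters, cell wall integrity, bud site selection, ASH1 mRNA localization, G2 and mitosis genes, sporulation genes, drug resistance transporters and nonsense-mediated decay. The alpha-specific genes and the auxotrophic markers had 4 measured genes each and were not tested as lists. Chromosome shifts were tested with limma on the mean log2 value of each of 16 chromosomes per array (5607 genes), adjusted over 176 tests and called at adjusted p under 0.05 with a shift of at least 0.2. Similarity was the Pearson correlation of log2 differences over 5656 genes, with exact permutation tests over all pairings of 10 strains and the 330 choices of 4 strains among 11, and 200 simulations of unchanged strains that share their controls.

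Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the deleted gene and its paralog, and the 5 highest and 5 lowest changes among called genes with 1 name whose arrays did not overlap between the 2 strains, from each comparison of 2 strains. It took up to 10 and 10 for the mean of the deletions (at least 9 strains on the same side) and for large against small subunit deletions, and up to 4 members of each list with the largest changes.

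The steps were tested on simulated data of the same size. In rpl7b against wild type limma called 10% of changed probe sets at 1.5-fold, 36% at 2-fold, 82% at 4-fold and 92% at 8-fold, with 7 of 117 calls false. In rps18a, where nothing was changed, it made 0 calls. For large against small subunit deletions it called 48%, 80%, 96% and 100%, with 10 false calls. A list raised by 0.3 gave a camera adjusted p of 6.01e-20 with 0 other calls, but correlated genes were not simulated. A chromosome raised 1.5-fold read 0.62. Exact permutation p for paralogs was 0.00106 with a shared part and 0.569 without.

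Alternatives were no normalization, median centring, a floor at the 25th percentile (14.1), log2(value + 1), leaving out the dimmest 25% of probe sets, limma's trend and robust options, only the 4 arrays compared, the replicate number as a block, leaving out each array or strain in turn, an estimated correlation, lists without the deleted genes, Spearman correlation, and changes against the mean of the deletions or with the controls split. Runs without the probe sets or genes of chromosomes XVI, V and VIII, on protein-coding genes alone, without rpl7a, rpl12b and rpl14a together, and with shared probe sets added to the lists were chosen after seeing the data. Samples of all 12 strains were used, and nothing was left out but the control probe sets. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.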

Results

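Gene expression was measured in wild-type budding yeast and in 11 strains that each lacked 1 ribosomal protein gene, with 2 biological replicates per strain. Most ribosomal protein genes of this yeast exist as a pair of near-identical copies (paralogs), and the design asks whether the copies of a pair differ in what their loss does to the cell. A gene of the large ribosomal subunit was missing in 7 strains (rpl7a, rpl7b, rpl12a, rpl12b, rpl14a, rpl22a and rpl22b) and a gene of the small subunit in 4 (rps0a, rps0b, rps18a and rps18b), so that 5 pairs had each copy deleted in a strain of its own. The wild type was BY4741, a haploid of mating type a, and cultures were harvested in early log phase in rich medium at 30 °C. On the arrays, 68.0% to 87.8% of probe sets lay above the background. Correlations between the 2 replicates of a strain ranged from 0.958 in rps0a to 0.981. In 8 of the 12 strains, wild type among them, an array of another strain correlated more highly than the replicate did (0.980 against 0.958 in rps0a). Differences below are on the log2 scale ± SE, signals are means ± SD over 2 arrays, and p values are adjusted over the 9275 probe sets of a comparison unless stated otherwise. Where a gene was not above the background in 1 of the strains compared, its change is given as a bound ("at least N-fold"), the ratio of the brighter strain's signal to the background of the dimmer one.

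The deletions were visible in the arrays. Of the deleted genes with a probe set of their own, 7 of 7 fell in their own strain: RPL7A (YGL076C) at -6.19 ± 0.15 in rpl7a, RPL14A (YKL006W) at -5.29 ± 0.14, RPL22A (YLR061W) at -7.49 ± 0.15, RPS0A (YGR214W) at -9.69 ± 0.29 and RPS0B (YLR048W) at -6.32 ± 0.14. Of 2 other RPL7A probe sets, 1 fell (-7.19 ± 0.18) and 1 stood at 0.82 ± 0.45 (adjusted p = 0.345). RPL7B (YPL198W) was at least 65.3-fold lower in rpl7b and RPL22B (YFL034C-A) at least 57.6-fold lower in rpl22b. The RPL12 and RPS18 copies share their probe sets. Of those naming both RPL12 copies, 1 was at least 606-fold lower in rpl12a and another at least 662-fold lower in rpl12b. The single RPS18 probe set fell in rps18a (-0.58 ± 0.11, adjusted p = 0.0271) and in rps18b (-0.55 ± 0.11, adjusted p = 0.0483). Beyond the deleted genes, 1 probe set with no gene name changed the same way in all 11 strains, from signals of 0.6 and 0.8 in the wild-type arrays to 6609.5 to 9578.8 in the 22 arrays of the deletions. Singled out after its values were seen, it counts in each comparison with wild type. Its sequence is not known, and whether it reports a yeast gene or the deletion construct was not tested.

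**Figure D1:**
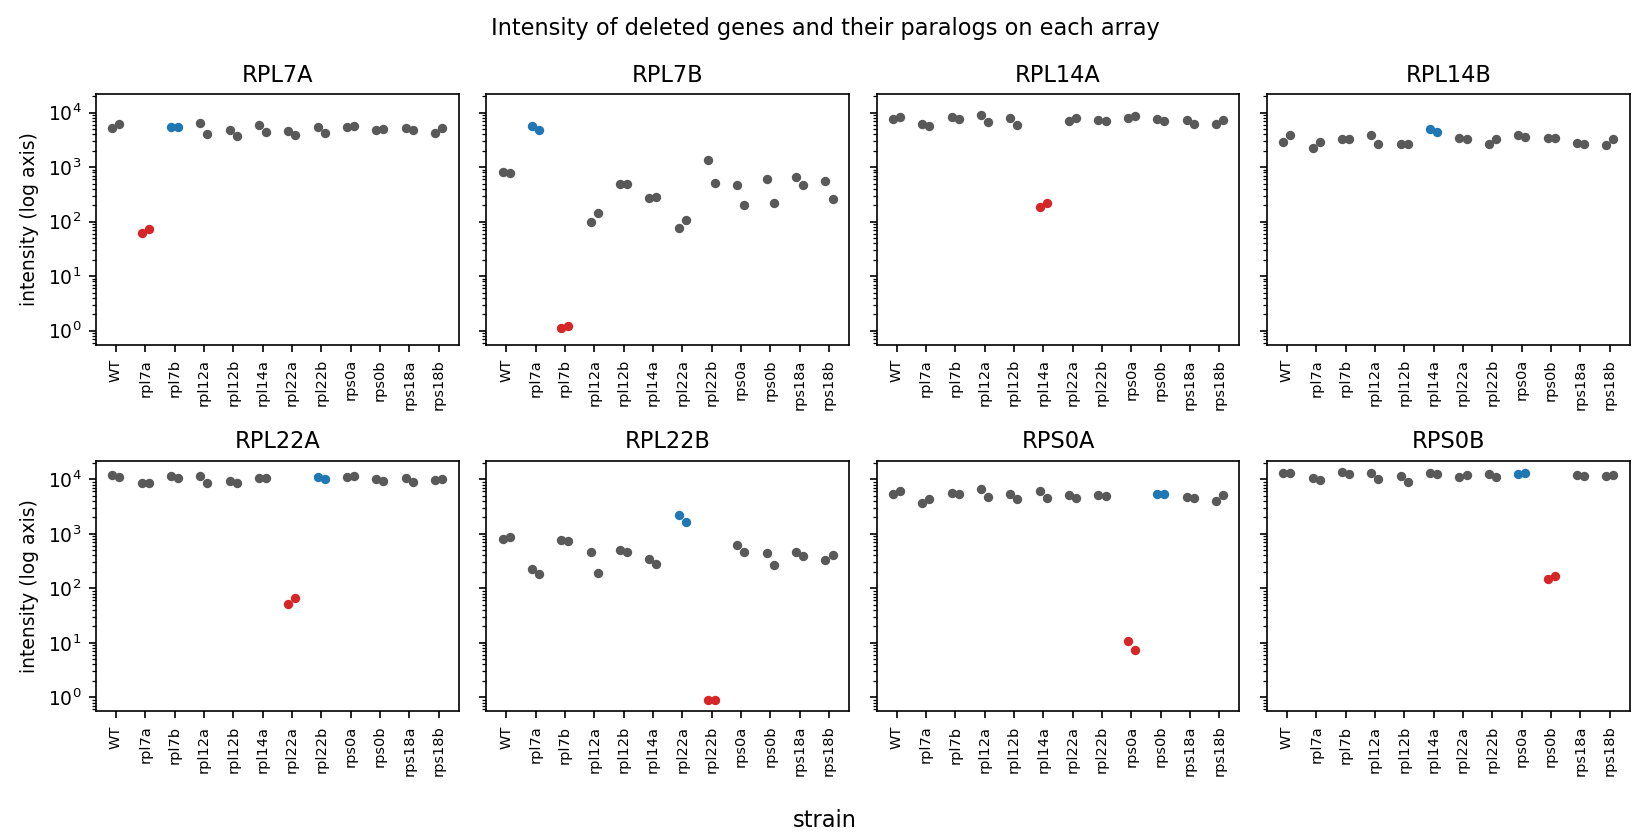
Signal (log axis, deposited intensity units) of RPL7A, RPL7B, RPL14A, RPL14B, RPL22A, RPL22B, RPS0A and RPS0B in each of the 24 arrays, 1 panel per gene, with the gene's own deletion in red, the deletion of its paralog in blue and all other strains in grey. Genes fall in their own deletion strain, and RPL7B and RPL22B lie higher in the strain that lacks the other copy.

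The remaining copy rose in 2 of the 7 deletions in which a probe set carried its name alone. RPL7B rose by 3.21 ± 0.57 in rpl7a, from 791 ± 9.90 to 5239 ± 625 (adjusted p = 0.00368, 0.000208 adjusted over the paralogs alone), and RPL22B rose by 1.48 ± 0.19 in rpl22a (adjusted p = 0.00106, 1.84e-05 over the paralogs alone). RPL14B differed by 0.56 ± 0.16 in rpl14a (0.0808, 0.00889 over the paralogs alone). RPL7B and RPL14B lie on chromosomes with means of 0.89 and 0.77 in these strains (below), and RPL14B did not exceed its own. RPL7A differed at -0.01 ± 0.15 in rpl7b, RPL22A by 0.07 ± 0.15 in rpl22b, RPS0B by 0.04 ± 0.14 in rps0a and RPS0A by 0.10 ± 0.29 in rps0b. Over the paralogs alone, p was 0.959, 0.922, 0.922 and 0.922. Without normalization 1 of the 2 rises passed.

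Whole chromosomes were higher in 3 strains. In rpl7a the genes of chromosome XVI, which carries RPL7B, lay 0.89 ± 0.06 above wild type on average (adjusted p = 1.08e-13), a median fold of 1.96 among its 351 genes above background, 96.6% of which were higher. In rpl12b the genes of chromosome V, which carries RPL12A, lay 0.88 ± 0.06 higher (adjusted p = 3.62e-13, median fold 1.93, 97.6% of 209 genes higher). In rpl14a those of chromosome VIII, which carries RPL14B, lay 0.77 ± 0.06 higher (adjusted p = 8.34e-12, median fold 1.77, 94.0% of 200 genes higher). The shift was present on both arms (medians 0.92 and 1.00 for XVI, 0.95 and 0.96 for V, 0.66 and 0.83 for VIII) and in both arrays of each strain (0.90 and 0.89, 0.86 and 0.90, 0.84 and 0.70). These were the 3 called of 176 tests of a chromosome in a strain, and the other means lay between -0.15 and 0.14. The chromosome held 216 of the 332 probe sets called higher in rpl7a (65.1%), 104 of 139 in rpl12b (74.8%) and 89 of 175 in rpl14a (50.9%).

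**Figure D2:**
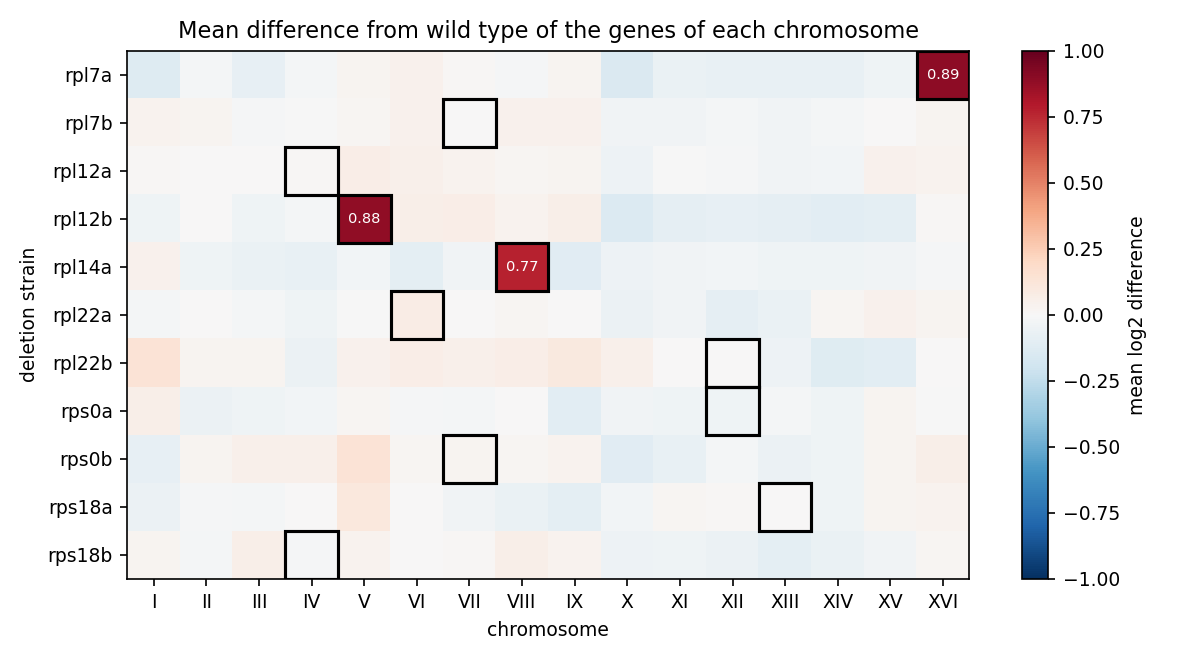
Mean log2 difference from wild type of the genes of each of the 16 chromosomes (columns) in each of the 11 deletion strains (rows), with the called values printed and the chromosome of the remaining copy boxed in black. Chromosome XVI in rpl7a, V in rpl12b and VIII in rpl14a stand out from the rest.

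Loss of RPL7A was accompanied by higher TPO2, a polyamine exporter of the plasma membrane (4.21 ± 0.63, adjusted p = 0.00148), HSP12, a membrane protein of the stress response (3.52 ± 0.83, 0.0205), and HPF1, a mannoprotein of the cell wall (2.77 ± 0.38, 0.000764). SNT309, a splicing factor encoded on chromosome XVI, was at least 6.28-fold higher. PHO84, the high-affinity phosphate transporter, fell by 6.19 ± 1.12, from 2629 ± 781 to 28.4 ± 2.40 (adjusted p = 0.00427). YAR068W was at least 20.5-fold lower. SNR39, a snoRNA encoded in an intron of RPL7A, was at least 5.16-fold lower, and SPL2, a regulator of low-affinity phosphate uptake, at least 6.21-fold. Of the 19 genes of the phosphate regulon, 6 fell and 2 rose (12 and 3 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.000740, adjusted p = 0.232 with an estimated correlation). Among them the acid phosphatase PHO5 fell by 1.74 ± 0.35, and PHM8 rose by 1.51 ± 0.28. Genes of the pheromone response fell, 5 of 29 (8 over the list alone, median -0.36, adjusted p = 0.000406, adjusted p = 0.398 with an estimated correlation), among them AGA1, the anchor subunit of a-agglutinin (-1.84 ± 0.26), and PRM1 (-1.66 ± 0.31). The a-specific genes fell as well, 2 of 7 (4 over the list alone, median -0.62, adjusted p = 0.000760, adjusted p = 0.146 with an estimated correlation): AGA2, the binding subunit of a-agglutinin, at -1.38 ± 0.21 and BAR1, the protease that degrades alpha-factor, at -1.29 ± 0.15.

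In rpl7a, 6 of 73 mitochondrial ribosomal protein genes rose (6 over the list alone, median 0.19, adjusted p = 0.0176, adjusted p = 0.809 with an estimated correlation), among them MRPS16 (1.98 ± 0.27) and MRPL51 (1.88 ± 0.23) of chromosome XVI. Of 37 proteasome genes 4 rose (6 over the list alone), among them PRE2 (1.49 ± 0.24) and RPN7 (1.29 ± 0.16), also of XVI, with a list median of 0.36 that was -0.03 without normalization and 0.15 relative to the median of all probe sets (adjusted p = 9.34e-05, adjusted p = 0.605 with an estimated correlation). Of 129 ribosome biogenesis genes 11 rose (12 over the list alone), among them RRP15 (2.06 ± 0.55), JIP5 (1.59 ± 0.18) and NOP4 (1.54 ± 0.36), again of XVI, with a list median of 0.17 that was -0.07 without normalization and 0.10 relative to the median of all probe sets (adjusted p = 0.00205, adjusted p = 0.703 with an estimated correlation). With the genes of chromosomes XVI, V and VIII left out, adjusted p was 0.00554 for the mitochondrial ribosomal proteins, 1.16e-06 for the proteasome and 0.0111 for ribosome biogenesis. The amino acid list then lost its call (0.0730), and large subunit ribosomal proteins were called lower (0.0299, against 0.104 with all genes). Amino acid biosynthesis genes fell more often than they rose, 7 against 3 of 74 (10 and 3 over the list alone, median -0.20, adjusted p = 0.0310, adjusted p = 0.703 with an estimated correlation), with BAT2, a branched-chain aminotransferase, at -1.61 ± 0.15 and GDH1, a glutamate dehydrogenase, at -0.97 ± 0.23. In all, 609 probe sets changed in rpl7a, 332 higher and 277 lower. The split was 88 higher and 279 lower of 367 without normalization and 248 and 347 of 595 with median centring. Without the probe sets of chromosome XVI it was 82 and 218 of 300, in a run chosen after seeing the data. The count was 232 or 330 without wild type replicate 1 or 2 and 311 or 327 without rpl7a replicate 1 or 2.

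Loss of the other copy, RPL7B, changed 3 probe sets: the 2 of RPL7B, and the unnamed probe set that rose in all deletions. These are named here after their values were seen. At an unadjusted p under 0.05 limma gave 248, where 464 would be expected by chance. No member of the lists called in this strain passed over all genes tested, apart from RPL7B itself. The iron regulon lay at a median of -0.28 over 32 genes (camera adjusted p = 1.08e-05, adjusted p = 0.283 with an estimated correlation) and the seripauperins and anaerobic wall proteins at -0.27 over 16 (adjusted p = 0.000156, adjusted p = 0.361 with an estimated correlation). The phosphate regulon lay at 0.20 (0.00335, adjusted p = 0.329 with an estimated correlation), the mitochondrial ribosomal proteins at 0.15 (0.00182, 0.703 with an estimated correlation) and the proteasome at 0.12 (0.00576, 0.710 with an estimated correlation). The count rose to 13 without wild type replicate 1 or 2 and to 6 without rpl7b replicate 2.

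Set against each other, the rpl7a and rpl7b strains differed at 496 probe sets, 279 higher and 217 lower in rpl7a. TPO2 was higher in rpl7a (adjusted p = 0.00160), as were OSI1 (3.06 ± 0.60) and SPC29, a spindle pole body component (2.85 ± 0.63). PHO84 was lower (-6.82 ± 1.12), and SPL2 at least 10.6-fold. SNT309 was at least 5.91-fold higher, and YAR068W and SNR39 at least 19.3-fold and 4.17-fold lower. Phosphate regulon genes were lower in rpl7a, 10 of 19, and 2 were higher (median -0.75, camera adjusted p = 6.14e-06, adjusted p = 0.143 with an estimated correlation), with VTC4, of polyphosphate synthesis, at -1.84 ± 0.27. Pheromone response genes were lower too, 6 of 29 (median -0.45, adjusted p = 2.03e-05, adjusted p = 0.437 with an estimated correlation; AGA1 -1.88 ± 0.26, PRM1 -1.85 ± 0.31). The a-specific genes were lower in 2 of 7 (median -0.56, adjusted p = 0.00149, adjusted p = 0.320 with an estimated correlation; AGA2 -1.46 ± 0.21, BAR1 -1.34 ± 0.15). Ribosome biogenesis genes were higher, 11 of 129, with a median of 0.16 that was -0.03 without normalization and 0.07 relative to the median of all probe sets (adjusted p = 0.0361, adjusted p = 0.866 with an estimated correlation). So were 2 of 37 proteasome genes, with a median of 0.22 that was -0.05 without normalization, -0.02 with median centring and 0.05 relative to the median of all probe sets (adjusted p = 0.0114, adjusted p = 0.795 with an estimated correlation). Chromosome XVI differed between the strains by 0.87 ± 0.06 (adjusted p = 1.19e-13). The split was 57 higher and 98 lower of 155 without normalization and 190 and 278 of 468 with median centring. Without the probe sets of XVI it was 54 and 160 of 214. Without the genes of XVI, V and VIII the ribosome biogenesis list lost its call (0.155), and sulfur and methionine metabolism (0.00420) and large subunit ribosomal proteins (0.0399) were called lower. Leaving out 1 array gave 259 (rpl7a replicate 1), 222 (rpl7a replicate 2), 148 (rpl7b replicate 1) or 231 (rpl7b replicate 2).

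In rpl12a, ARG4 (1.28 ± 0.13, adjusted p = 0.000202) and ARG7 (0.93 ± 0.17, 0.0326), of arginine synthesis, rose, while ARG1 stood at 1.38 ± 0.54 (adjusted p = 0.459). Also higher were GCV1, of the glycine cleavage complex (1.40 ± 0.25), IZH4 (1.70 ± 0.25) and EMC10 (0.92 ± 0.17). PHO5 (-2.13 ± 0.35), VTC3, of polyphosphate synthesis (-1.99 ± 0.34), the wall mannoprotein TIR1 (-1.62 ± 0.28) and the ribosomal protein genes RPL9B (-1.61 ± 0.29) and RPL22B (-1.30 ± 0.19) fell. Of the 74 amino acid biosynthesis genes 2 rose (20 rose and 1 fell over the list alone), with a median of 0.27 (camera adjusted p = 8.85e-13, adjusted p = 0.0909 with an estimated correlation). Of the phosphate regulon 2 fell (3 over the list alone, median -0.40, adjusted p = 1.44e-08, adjusted p = 0.0834 with an estimated correlation). Lists with no member past the threshold over all genes lay at 0.29 for oxidative phosphorylation (5.69e-05, adjusted p = 0.591 with an estimated correlation), 0.18 for ribosome biogenesis (0.000251, adjusted p = 0.664), 0.18 for RNA polymerases I and III (0.0413, 0.703), 0.14 for the proteasome (0.0253, 0.809), -0.11 for mitochondrial ribosomal proteins (0.0385, 0.829), -0.13 for heat shock factor chaperones (0.0474, 0.829) and -0.22 for the pheromone response (0.0431, 0.703), the second value again with an estimated correlation. The seripauperins and anaerobic wall proteins, with TIR1 lower, lay at -0.22 (0.00438, adjusted p = 0.569 with an estimated correlation). The strain had 27 changed probe sets, 10 higher and 17 lower, against 797 at an unadjusted p under 0.05. The split was 1 and 15 of 16 without normalization and 6 and 20 of 26 with median centring. With the replicate number as a block it was 31 and 25 of 56, and with limma's trend and robust options 18 and 26 of 44. The count was 17 without rpl12a replicate 2.

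In rpl12b, SMB1, a core protein of spliceosomal snRNPs (1.84 ± 0.37), EAF5, a subunit of the NuA4 acetyltransferase (adjusted p = 0.0120), and TDA2 (1.75 ± 0.18), all of chromosome V, rose, as did MFB1 (1.75 ± 0.37). SNT309 was at least 3.26-fold higher. PHO3, an acid phosphatase (-1.64 ± 0.37), VTC3 (-1.59 ± 0.34) and TDH1, a glyceraldehyde-3-phosphate dehydrogenase (-1.59 ± 0.30), fell. IRC4 and the non-coding YNCD0014C were at least 1.69-fold and 1.44-fold lower. The phosphate regulon had 3 lower and 1 higher of 19 (6 and 3 over the list alone, median -0.60, camera adjusted p = 0.00749, adjusted p = 0.398 with an estimated correlation). The iron regulon had 3 lower of 32 (10 over the list alone, median -0.62, adjusted p = 1.34e-06, adjusted p = 0.221 with an estimated correlation). Of 25 purine and one-carbon genes 3 fell and 1 rose (9 and 2 over the list alone, median -0.38, adjusted p = 0.00311, adjusted p = 0.558 with an estimated correlation), with ADE17, of purine synthesis, at -1.15 ± 0.25 and GCV1 higher (adjusted p = 0.00576). The a-specific genes had none past the threshold over all genes and 6 of 7 lower over the list alone (median -0.63, adjusted p = 2.69e-05, adjusted p = 0.0909 with an estimated correlation). The pheromone response had 1 lower of 29 (median -0.29, 0.0224, adjusted p = 0.643 with an estimated correlation). Of the proteasome genes 3 rose, all of chromosome V: PUP3 (1.18 ± 0.14), RPN3 (1.12 ± 0.19) and PRE1 (1.08 ± 0.24), with a list median of 0.23 (0.000760, adjusted p = 0.664 with an estimated correlation). The induced genes of the environmental stress response had a median of -0.24 (0.0210, adjusted p = 0.737 with an estimated correlation), although the 3 past the threshold rose, GLC3, the glycogen branching enzyme (1.49 ± 0.32), and SSA4, an Hsp70 chaperone (1.40 ± 0.33), of chromosome V among them. The COS and helicase subtelomeric families lay at -0.41 over 7 genes (0.0385, adjusted p = 0.651 with an estimated correlation, and 0.121 without the genes of XVI, V and VIII). In all 195 probe sets changed, 139 higher and 56 lower. Without the probe sets of chromosome V, a run chosen after seeing the data, 16 were higher and 18 lower of 34. The split was 2 and 8 of 10 without normalization and 80 and 43 of 123 with median centring. The count was 54, 77 or 61 without wild type replicate 1, wild type replicate 2 or rpl12b replicate 2.

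Between the rpl12 strains, HPF1 (2.39 ± 0.38), ARO10, a decarboxylase of amino acid breakdown (1.97 ± 0.37), RTC3 (1.94 ± 0.29) and PNS1 (1.88 ± 0.40) were higher in rpl12a, and GRE1 at least 1.33-fold. Lower in rpl12a were MIG3 (-2.47 ± 0.55), TIR1 (-1.97 ± 0.28), THO1 (-1.77 ± 0.18) and SSA4 (-1.70 ± 0.33), all of chromosome V, and PDR15, an ABC transporter of drug resistance (-1.71 ± 0.30). Amino acid biosynthesis genes were higher in 5 and lower in 3 of 74 (15 and 6 over the list alone, median 0.27, camera adjusted p = 0.00122, adjusted p = 0.625 with an estimated correlation; LEU4 1.54 ± 0.33, ARG4 1.08 ± 0.13). Iron regulon genes were higher in 2 of 32 (8 over the list alone, median 0.44, 1.97e-05, adjusted p = 0.437 with an estimated correlation): ENB1, a siderophore transporter, by 1.41 ± 0.21 and VHT1, the biotin transporter, by 1.30 ± 0.22. The a-specific genes were higher in 2 of 7 (4 over the list alone, median 0.90, 4.07e-05, adjusted p = 0.128 with an estimated correlation), the a-factor genes MFA1 (1.47 ± 0.31) and MFA2 (0.91 ± 0.16). Of the purine and one-carbon genes 1 was higher, AAH1 (1.30 ± 0.27), and 8 over the list alone (median 0.28, 0.000392, adjusted p = 0.545 with an estimated correlation). Induced stress response genes were higher in 2 and lower in 2 of 61 (12 and 2 over the list alone, median 0.21, 0.000169, adjusted p = 0.625 with an estimated correlation). Mitochondrial ribosomal protein genes were lower in 2 of 73, RSM18 (-1.24 ± 0.19) and RML2 (-1.08 ± 0.19) of chromosome V (median -0.27, 0.000502, adjusted p = 0.742 with an estimated correlation). Further medians were 0.41 for oxidative phosphorylation (0.000502, 0.742 with an estimated correlation), 0.59 for the COS families, with COS8 at 1.33 ± 0.29 (0.0171, 0.636 with an estimated correlation, and 0.106 without the genes of XVI, V and VIII), -0.31 for heat shock factor chaperones (0.00673, 0.792 with an estimated correlation) and -0.27 for G1 and S phase genes (0.0161, 0.625 with an estimated correlation). Chromosome V differed at -0.82 ± 0.06 (adjusted p = 1.39e-12). The strains differed at 153 probe sets, 51 higher and 102 lower in rpl12a. The split was 11 and 13 of 24 without normalization, 32 and 59 of 91 with median centring, 128 and 175 of 303 with the replicate block and 27 and 21 of 48 without the probe sets of V. The count was 73, 36 or 65 without rpl12a replicate 1, rpl12a replicate 2 or rpl12b replicate 2.

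The rpl14a strain showed lower expression of genes specific to a cells. AGA2 (-3.04 ± 0.21, adjusted p = 2.33e-06), BAR1 (-2.87 ± 0.15, 8.87e-08) and the a-factor gene MFA1 (-2.34 ± 0.31) fell. ASG7 was at least 5.23-fold lower. Of the 7 a-specific genes 6 fell (6 over the list alone), with a median of -2.34 (camera adjusted p = 5.76e-14, adjusted p = 0.0109 with an estimated correlation). Pheromone response genes fell, 8 of 29 (11 lower and 1 higher over the list alone, median -0.55, 3.45e-09, adjusted p = 0.0994 with an estimated correlation), among them the mating genes FUS1 (-2.63 ± 0.32) and PRM1 (-2.36 ± 0.31), and FIG1 at least 2.95-fold. Of 28 daughter cell and M/G1 genes 3 fell and 1 rose (8 and 1 over the list alone, median -0.19, 0.0474, adjusted p = 0.414 with an estimated correlation), FAR1, which arrests the cycle in response to pheromone, at -1.83 ± 0.19 and DSE2 by 1.27 ± 0.21.

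Phosphate genes moved upward in rpl14a. PHO89, the sodium-phosphate cotransporter, rose by 3.88 ± 0.35 (adjusted p = 3.15e-05), SPL2 by 3.86 ± 0.63 (0.00383) and PHM6 by 2.11 ± 0.36, and PHO84 stood at 1.69 ± 1.12 (adjusted p = 0.542). Of the 19 phosphate regulon genes 9 rose (11 over the list alone), with a median of 1.14 (camera adjusted p = 1.18e-10, adjusted p = 0.0738 with an estimated correlation). TPO2 rose by 2.78 ± 0.63, IRC18 was at least 3.32-fold and CRC1, a mitochondrial carnitine carrier, at least 1.73-fold higher. Amino acid biosynthesis genes rose, 15 of 74 (22 higher and 1 lower over the list alone, median 0.34, 4.05e-11, adjusted p = 0.0994 with an estimated correlation): ARO9 (1.81 ± 0.41) and ARG4 (1.79 ± 0.13), both of chromosome VIII, and LYS1 (1.41 ± 0.19). Ribosome biogenesis genes rose, 12 of 129 (21 over the list alone, median 0.37, 5.76e-14, adjusted p = 0.201 with an estimated correlation), with UTP9 (1.96 ± 0.20), RRP3 (1.79 ± 0.18) and IMP3 (1.75 ± 0.20) on chromosome VIII. With the genes of chromosomes XVI, V and VIII left out, adjusted p was 5.32e-11 for ribosome biogenesis and for amino acid biosynthesis, 3.82e-07 for the phosphate regulon and 4.77e-15 for the a-specific genes. Of 26 ergosterol genes 3 rose (4 over the list alone), ERG9 (1.10 ± 0.23), NCP1 (0.97 ± 0.19) and ERG7 (0.94 ± 0.20), all of VIII (0.0156, adjusted p = 0.605 with an estimated correlation, and 0.151 without the 3 chromosomes). RNA polymerases I and III had 1 higher, RPC10 of VIII (0.88 ± 0.19), with a list median of 0.37 (0.000674, adjusted p = 0.427 with an estimated correlation). The proteasome had 1 higher, ECM29 (1.11 ± 0.26; median 0.15, 0.0105, adjusted p = 0.763 with an estimated correlation). Mitochondrial ribosomal proteins lay at -0.32 (0.00242, adjusted p = 0.703 with an estimated correlation) and G1 and S phase genes at -0.33 (0.0385, adjusted p = 0.633 with an estimated correlation, and 0.107 without the 3 chromosomes). Without them oxidative phosphorylation was called higher (0.0370, against 0.0553 with all genes). Of all probe sets 310 changed, 175 higher and 135 lower. Without the probe sets of chromosome VIII, a run chosen after seeing the data, 69 were higher and 102 lower of 171. The split was 58 and 32 of 90 without normalization, 107 and 79 of 186 with median centring and 266 and 211 of 477 with the replicate block. The count was 99, 128, 169 or 137 without wild type replicate 1, wild type replicate 2, rpl14a replicate 1 or rpl14a replicate 2.

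In rpl22a, amino acid biosynthesis genes rose, 23 of 74 (37 higher and 1 lower over the list alone, median 0.48, camera adjusted p = 7.54e-18, adjusted p = 0.0801 with an estimated correlation). Arginine genes were among them, ARG1 at 2.26 ± 0.54, ARG4 at 1.98 ± 0.13 and ARG7 at 1.93 ± 0.17, while ARG3 stood at 2.04 ± 0.53 with adjusted p = 0.0627. GCV1 rose by 2.24 ± 0.25 and HPF1 by 2.22 ± 0.38. SNT309 and GAS4, a spore wall glucanosyltransferase, were at least 3.44-fold and 2.22-fold higher. Phosphate regulon genes fell, 8 of 19 (9 over the list alone, median -0.61, 2.34e-07, adjusted p = 0.0859 with an estimated correlation): PHO84 at -5.13 ± 1.12, SPL2 at -3.18 ± 0.63 and PHO5 at -2.23 ± 0.35. RPL7B, a ribosomal protein gene of another pair, fell by 2.84 ± 0.57 (adjusted p = 0.0169), and the mating gene FIG1 was at least 3.20-fold lower. Ribosome biogenesis genes rose, 6 of 129 (7 over the list alone, median 0.28, 1.23e-07, adjusted p = 0.447 with an estimated correlation). The proteasome had a median of 0.19 that was -0.03 without normalization and 0.07 relative to the median of all probe sets (0.0121, adjusted p = 0.765 with an estimated correlation), with no member past the threshold. Changed were 227 probe sets, 132 higher and 95 lower. The split was 33 and 49 of 82 without normalization and 216 and 158 of 374 with the replicate block. The count was 97, 112 or 97 without wild type replicate 1, wild type replicate 2 or rpl22a replicate 2.

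Loss of RPL22B changed 2 probe sets, RPL22B itself and the unnamed probe set that rose in all deletions, named here after their values were seen, against 400 at an unadjusted p under 0.05 in limma. Ribosomal protein genes of the large subunit lay at a median of -0.10 over 47 genes (camera adjusted p = 0.000674, adjusted p = 0.294 with an estimated correlation), and those of the small subunit at -0.06 over 34 (0.0463, adjusted p = 0.558 with an estimated correlation). Translation factors lay at -0.14 over 33 (0.0310, adjusted p = 0.643 with an estimated correlation). Apart from RPL22B, no member of the 3 lists passed over all genes. The count was 14, 9, 27 or 6 without wild type replicate 1, wild type replicate 2, rpl22b replicate 1 or rpl22b replicate 2, and 5 with a floor at the 25th percentile. Without normalization the split was 1 higher and 2 lower of 3.

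The direct comparison of the rpl22 strains gave 262 probe sets, 161 higher and 101 lower in rpl22a. ARG1 (2.55 ± 0.54), the aromatic amino acid gene ARO10 (2.31 ± 0.37), ARO5 (2.46 ± 0.31) and the mitochondrial cytochrome b gene COB (2.38 ± 0.44) were higher in rpl22a. PHO84 (-5.64 ± 1.12), SPL2 (-3.92 ± 0.63) and RPL7B (-3.18 ± 0.57) were lower, as was FIG1, at least 4.52-fold. Amino acid biosynthesis genes were higher in 24 of 74 (39 higher and 1 lower over the list alone, median 0.52, camera adjusted p = 2.64e-15, adjusted p = 0.0945 with an estimated correlation; ARG7 2.14 ± 0.17, LYS1 1.72 ± 0.19). Phosphate regulon genes were lower in 9 of 19 (11 over the list alone, median -0.84, 2.80e-09, adjusted p = 0.0945 with an estimated correlation; PHO5 -2.55 ± 0.35). Ribosome biogenesis genes were higher in 7 of 129 (11 over the list alone, median 0.36, 2.80e-09, adjusted p = 0.545 with an estimated correlation; RLP7 1.42 ± 0.28). Smaller groups were RNA polymerases I and III with RPC11 higher (0.92 ± 0.19; list 0.0251, adjusted p = 0.742 with an estimated correlation), the proteasome with RPN8 higher (0.89 ± 0.19; list 0.0272, adjusted p = 0.845 with an estimated correlation), mitochondrial ribosomal proteins with MRP4 (-1.55 ± 0.39) and MRPL13 (-0.76 ± 0.16) lower (list 0.00673, adjusted p = 0.795 with an estimated correlation) and induced stress response genes with 2 lower, GAD1 (-1.36 ± 0.29) among them (list 0.0272, adjusted p = 0.795 with an estimated correlation). The split was 46 and 28 of 74 without normalization, 78 and 81 of 159 with median centring and 251 and 161 of 412 with the replicate block. Leaving out rpl22a replicate 1, rpl22a replicate 2 or rpl22b replicate 2 gave 156, 106 or 136 probe sets.

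In rps0a, SNR6, the U6 spliceosomal RNA, rose by 1.94 ± 0.37 (adjusted p = 0.0485). GAS4 and the GATA factor gene GAT3 were at least 2.19-fold and 1.17-fold higher. FMP16 (-2.51 ± 0.42), PHO5 (-2.16 ± 0.35) and TDH1 (-1.73 ± 0.30) fell, and PHM6 was at least 2.07-fold lower. Induced genes of the environmental stress response fell, 4 of 61 (13 over the list alone, median -0.53, camera adjusted p = 4.14e-10, adjusted p = 0.191 with an estimated correlation), among them GAD1, a glutamate decarboxylase (-1.53 ± 0.29). Of the phosphate regulon 2 fell (6 over the list alone, median -0.45, 8.70e-08, adjusted p = 0.0834 with an estimated correlation). Of 21 glycolysis and fermentation genes 1 fell, TDH1 (4 over the list alone, median -0.13, mean -0.35, 0.0111, adjusted p = 0.605 with an estimated correlation). Ribosome biogenesis genes lay higher as a list (median 0.41, 6.72e-16, adjusted p = 0.163 with an estimated correlation) with none past the threshold singly. So did RNA polymerases I and III (median 0.30, 0.000674, adjusted p = 0.427 with an estimated correlation). Mitochondrial ribosomal proteins lay at -0.16 (0.0113, adjusted p = 0.796 with an estimated correlation), the citric acid cycle at -0.19 (0.0385, adjusted p = 0.691 with an estimated correlation) and the proteasome at 0.13, or -0.14 with median centring (0.0423, adjusted p = 0.829 with an estimated correlation). Changed were 27 probe sets, 8 higher and 19 lower, against 1095 at an unadjusted p under 0.05. The background of rps0a replicate 2 was 30.8 against 5.55 in replicate 1. The count was 459 without replicate 1, 11 without replicate 2 and 14 without wild type replicate 1. The split was 8 and 8 of 16 without normalization, 20 and 48 of 68 with median centring, 5 and 11 of 16 with log2(value + 1) and 17 and 28 of 45 with the replicate block.

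In rps0b, HXK1, a hexokinase (-3.40 ± 0.55, adjusted p = 0.00671), YGP1, a secreted glycoprotein (-2.82 ± 0.37), PHO84 (-5.41 ± 1.12) and SPL2 (adjusted p = 0.0280) fell. The snoRNA SNR52 (2.95 ± 0.40, adjusted p = 0.00196), SNR19, the U1 RNA (2.15 ± 0.45), and the non-coding YNCM0020W (2.82 ± 0.51) and YNCB0011C (2.61 ± 0.58) rose. GAS4 was at least 1.52-fold higher. Induced stress response genes fell, 16 of 61 (27 over the list alone, median -0.71, camera adjusted p = 6.25e-14, adjusted p = 0.0994 with an estimated correlation), with DDR48 at -2.35 ± 0.27. Ribosome biogenesis genes rose, 19 of 129 (42 over the list alone, median 0.64, 1.12e-26, adjusted p = 0.0834 with an estimated correlation). Genes of RNA polymerases I and III rose, 3 of 27 (8 over the list alone, median 0.36, 9.90e-06, adjusted p = 0.238 with an estimated correlation), with RRN3, an initiation factor of polymerase I, at 1.44 ± 0.27. Phosphate regulon genes fell, 7 of 19 (9 over the list alone, median -0.62, 6.68e-08, adjusted p = 0.0834 with an estimated correlation; PHO5 -2.28 ± 0.35, VTC3 -2.07 ± 0.34). Of the glycolysis and fermentation genes 4 fell (4 over the list alone, median -0.14, mean -0.53, 0.000784, adjusted p = 0.428 with an estimated correlation), with TDH1 at -2.11 ± 0.30, the glucokinase GLK1 at -1.97 ± 0.44 and ENO1 at -1.49 ± 0.24. Of 28 heat shock factor chaperones 5 fell (7 over the list alone, median -0.21, 0.00407, adjusted p = 0.703 with an estimated correlation; HSP42 -1.82 ± 0.39, HSP78 -1.37 ± 0.28, SSC1 -1.30 ± 0.16). Of 27 citric acid cycle genes 3 fell (4 over the list alone, median -0.20, 0.0103, adjusted p = 0.605 with an estimated correlation; MDH2 -1.01 ± 0.13). Mitochondrial ribosomal proteins lay at -0.22 (0.00147, adjusted p = 0.703 with an estimated correlation) and the pheromone response at -0.19 (0.0156, adjusted p = 0.619 with an estimated correlation). Of all probe sets 243 changed, 95 higher and 148 lower. The split was 15 and 61 of 76 without normalization, 69 and 190 of 259 with median centring, 54 and 81 of 135 with log2(value + 1) and 187 and 231 of 418 with the replicate block. The count was 49, 81, 89 or 57 without wild type replicate 1, wild type replicate 2, rps0b replicate 1 or rps0b replicate 2.

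Compared with each other, the rps0 strains differed at 8 probe sets, 3 higher and 5 lower in rps0a, with 784 at an unadjusted p under 0.05. RPS0A and RPS0B, the deleted genes, made up 4 of the 8. GAT3 was at least 1.22-fold higher in rps0a (adjusted p = 0.000731), YGL188C-A lay near the background in both strains, and the remaining 2 have no gene name and are singled out after their values were seen. As lists, ribosome biogenesis lay lower in rps0a (median -0.28, camera adjusted p = 2.15e-07, adjusted p = 0.573 with an estimated correlation), and the induced stress response (0.20, 0.00131, adjusted p = 0.730 with an estimated correlation), heat shock factor chaperones (0.11, 0.0234, adjusted p = 0.795 with an estimated correlation) and the pheromone response (0.18, 0.0272, adjusted p = 0.742 with an estimated correlation) lay higher, with no member past the threshold over all genes. Without rps0a replicate 1, 271 probe sets differed. The split was 4 and 3 of 7 without normalization and with median centring. With log2(value + 1), without the dimmest 25% of probe sets, or with limma's trend and robust options, 4 differed.

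In rps18a, SNR52 rose by 3.20 ± 0.40 (adjusted p = 0.00252), the tRNA gene SUF23 by 1.97 ± 0.26 and YNCP0022W by 1.69 ± 0.34. GAS4 and the tRNA gene EMT5 were at least 2.03-fold and 1.07-fold higher. GPH1, glycogen phosphorylase, was at least 2.69-fold lower, and HXK1 (-2.70 ± 0.55), YGP1 (-2.47 ± 0.37), FIT2, a siderophore-binding mannoprotein (-2.38 ± 0.45), and PHO5 (-2.28 ± 0.35) fell. Induced stress response genes fell, 5 of 61 (21 over the list alone, median -0.67, camera adjusted p = 5.76e-14, adjusted p = 0.0994 with an estimated correlation). Ribosome biogenesis had 1 gene higher of 129 (11 over the list alone, median 0.50, 1.73e-22, adjusted p = 0.0909 with an estimated correlation). RNA polymerases I and III had 1 of 27, RPA135 of polymerase I (0.63 ± 0.13), and 3 over the list alone (median 0.38, 4.32e-06, adjusted p = 0.223 with an estimated correlation). Of the phosphate regulon 1 gene, PHO5, fell (5 over the list alone, median -0.45, 2.25e-06, adjusted p = 0.0909 with an estimated correlation). Of the glycolysis and fermentation genes 2 fell, HXK1 and TDH1 (-2.27 ± 0.30), and 4 over the list alone (median -0.15, mean -0.48, 8.26e-05, adjusted p = 0.329 with an estimated correlation). Of the citric acid cycle 1 fell, MDH2 (-0.77 ± 0.13; list 0.0423, adjusted p = 0.703 with an estimated correlation). Mitochondrial ribosomal proteins lay at -0.22 (0.00147, adjusted p = 0.703 with an estimated correlation). The proteasome lay at 0.25, or -0.25 without normalization, -0.02 with median centring and 0.00 relative to the median of all probe sets (0.000450, adjusted p = 0.636 with an estimated correlation). Translation factors lay at 0.13, or -0.26, -0.03 and -0.01 (0.0385, adjusted p = 0.664 with an estimated correlation). Changed were 62 probe sets, 21 higher and 41 lower, against 1169 at an unadjusted p under 0.05. The split was 12 and 190 of 202 without normalization, 26 and 77 of 103 with median centring, 33 and 73 of 106 with a floor at the 25th percentile and 11 and 27 of 38 with log2(value + 1). It was 38 and 89 of 127 with limma's trend and robust options and 57 and 105 of 162 with the replicate block. The count was 21 without wild type replicate 1 and 23 without rps18a replicate 2.

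In rps18b the non-coding RNAs YNCM0020W (2.67 ± 0.51), SNR52 (2.49 ± 0.40), YNCP0022W (2.23 ± 0.34), SNR45 (2.09 ± 0.35) and SUF23 (1.92 ± 0.26) rose. PHO5 (-2.26 ± 0.35), TDH1 (-1.70 ± 0.30), the ribosomal protein gene RPS22B (-1.49 ± 0.19) and MRX9 (-1.42 ± 0.26) fell. UME1, a transcriptional regulator of meiotic genes, was at least 1.75-fold lower. Of the induced stress response genes 1 fell (5 over the list alone, median -0.45, camera adjusted p = 1.15e-07, adjusted p = 0.294 with an estimated correlation). Of the phosphate regulon 1 fell, PHO5 (5 over the list alone, median -0.48, 1.59e-06, adjusted p = 0.0909 with an estimated correlation). TDH1 was the glycolysis and fermentation gene past the threshold (list median -0.12, mean -0.32, 0.00752, adjusted p = 0.605 with an estimated correlation). Ribosome biogenesis lay at 0.41 with no member past the threshold (1.66e-17, adjusted p = 0.142 with an estimated correlation), and at -0.03 without normalization or 0.33 relative to the median of all probe sets. RNA polymerases I and III lay at 0.27, or -0.18 without normalization and 0.18 relative to that median (0.00295, adjusted p = 0.558 with an estimated correlation). The proteasome lay at 0.18, or -0.30 without normalization and 0.06 relative to that median (0.000391, adjusted p = 0.633 with an estimated correlation). Further medians were -0.19 for mitochondrial ribosomal proteins (0.00433, adjusted p = 0.737 with an estimated correlation), -0.18 for the iron regulon (0.0338, adjusted p = 0.703 with an estimated correlation) and -0.18 for oxidative phosphorylation (0.0422, adjusted p = 0.829 with an estimated correlation). Changed were 31 probe sets, 15 higher and 16 lower, against 983 at an unadjusted p under 0.05. The split was 6 and 58 of 64 without normalization and 22 and 26 of 48 with the replicate block. The count was 20, 17 or 16 without wild type replicate 1, rps18b replicate 1 or rps18b replicate 2.

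Between the rps18 strains 1 probe set differed, which has no gene name and is singled out after its value was seen (0.93, adjusted p = 0.0439), with 446 at an unadjusted p under 0.05. It no longer passed without normalization, with median centring, with log2(value + 1), without the dimmest 25% of probe sets, with limma's trend and robust options, with the replicate block or with only the 4 arrays compared, where the count was 0. With a floor at the 25th percentile it did not pass either, and the 1 probe set called there was lower in rps18a. As lists, the induced stress response lay lower in rps18a (median -0.21, camera adjusted p = 0.000390, adjusted p = 0.625 with an estimated correlation), as did the a-specific genes (-0.23, 0.00673, adjusted p = 0.437 with an estimated correlation). Translation factors (0.16, 0.0106, adjusted p = 0.625 with an estimated correlation) and RNA polymerases I and III (0.18, 0.0272, adjusted p = 0.742 with an estimated correlation) lay higher. The count was 9 (7 higher and 2 lower), 2 (1 and 1) or 6 (0 and 6) without rps18a replicate 1, rps18b replicate 1 or rps18b replicate 2.

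Across the 11 deletions, some lists were called in several strains. Ribosome biogenesis was called higher in 8 strains and lower in 0, the proteasome in 9 and 0, and RNA polymerases I and III in 6 and 0. The phosphate regulon was called lower in 8 and higher in 2, rpl7b and rpl14a, and mitochondrial ribosomal proteins lower in 6 and higher in 2. Induced stress response genes and the pheromone response were called lower in 5 strains each and higher in 0, and amino acid biosynthesis genes higher in 3, rpl12a, rpl14a and rpl22a, and lower in 1, rpl7a. The strains share the 2 wild-type arrays, so these counts are not independent. With an estimated correlation the calls of these 8 lists were lost. The lowest adjusted p over the strains was then 0.0834 for ribosome biogenesis, 0.605 for the proteasome, 0.223 for the polymerases, 0.0738 for the phosphate regulon and 0.703 for mitochondrial ribosomal proteins. It was 0.0994 for the stress and for the pheromone response and 0.0801 for amino acid biosynthesis. PHO84 had 7382 ± 154 in rpl14a against 2629 ± 781 in wild type. Its 2 rps18a arrays read 60.2 and 1478.1. In all comparisons 141 list calls were made, of which 14 had a median of the other sign under another scaling and 3 had it relative to the median of all probe sets (the proteasome in rps0a, translation factors in rps18a and the deleted genes with their paralogs in rpl7b). That last list, 8 genes that the study itself chose to delete and their paralogs, was called lower in 4 strains, with adjusted p of 0.0385 in rpl7a, 0.0217 in rpl7b, 0.0111 in rpl14a and 0.0204 in rps0b (0.233, 0.188, 0.143 and 0.186 with an estimated correlation), and is not independent evidence of a direction. The median of all probe sets lay between -0.36 (rps18b) and 0.20 (rps0a against rps0b) without normalization.

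**Figure D3:**
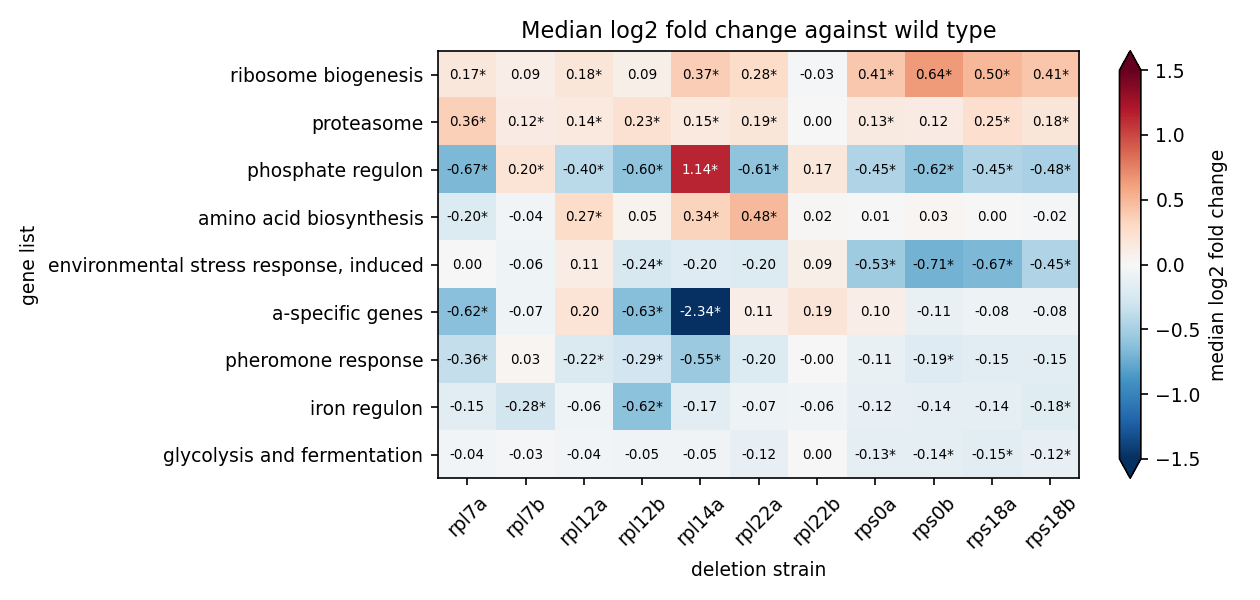
Median log2 difference from wild type of the genes of 9 lists (rows) in the 11 deletion strains (columns), with an asterisk where the camera adjusted p was under 0.05. Ribosome biogenesis lies above 0 in most strains and the phosphate regulon below 0 in most, with rpl14a the reverse for phosphate.

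**Figure D4:**
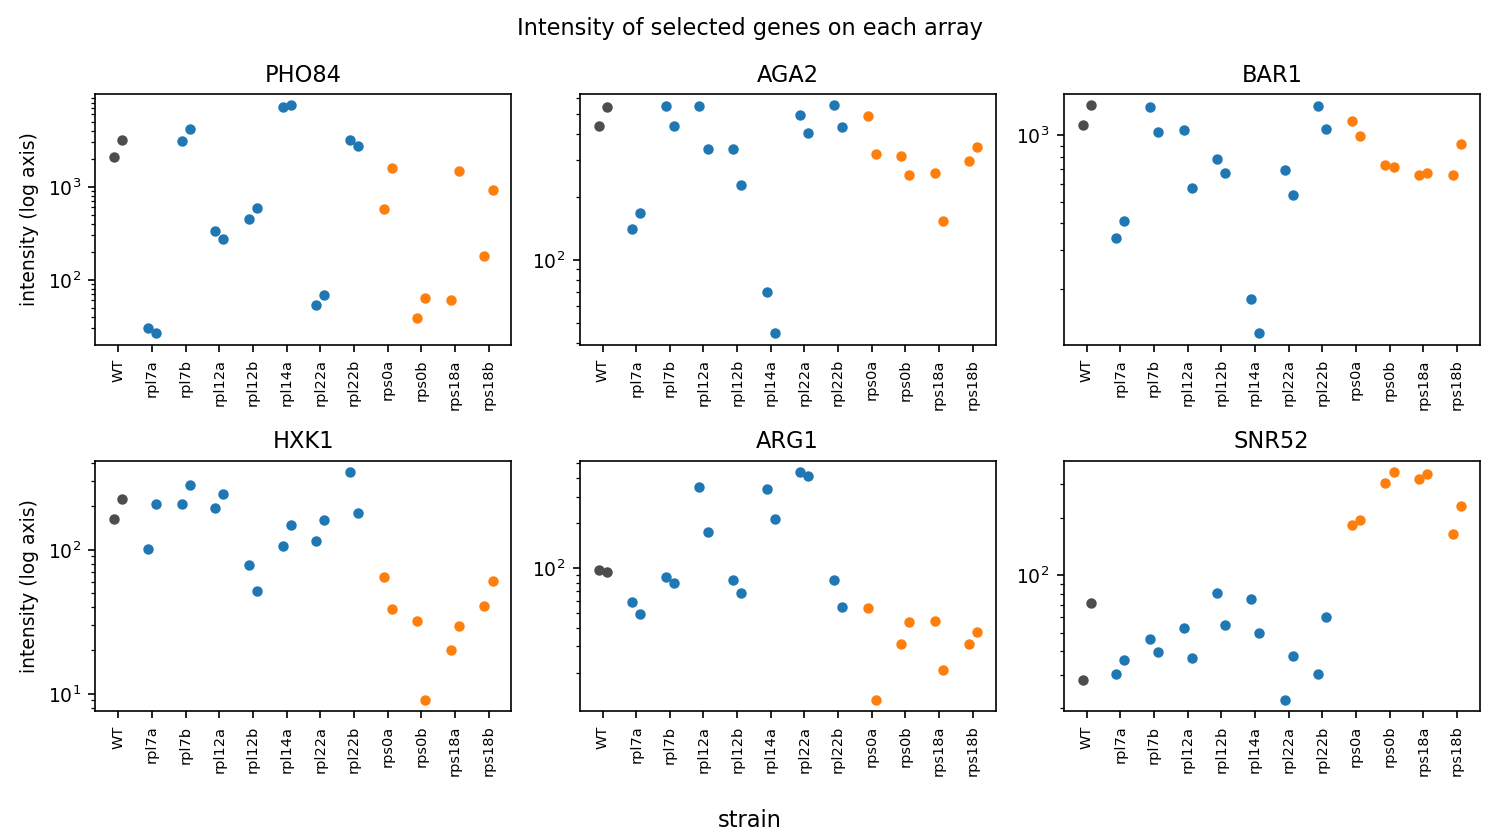
Signal (log axis, deposited intensity units) of PHO84, AGA2, BAR1, HXK1, ARG1 and SNR52 in the 24 arrays, by strain, with wild type in grey, large subunit deletions in blue and small subunit deletions in orange. AGA2 and BAR1 are low in rpl14a, HXK1 is lower and SNR52 higher in the small subunit deletions.

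The mean of the 11 deletions against wild type changed 38 probe sets, 10 higher and 28 lower. GCV1 (1.08 ± 0.19, adjusted p = 0.0293), YOR302W, the upstream reading frame of the arginine gene CPA1 (0.82 ± 0.16), IMP3, of the small subunit processome (0.76 ± 0.14), and POC4, a proteasome assembly factor (0.63 ± 0.12), rose. DAD1, a kinetochore protein (-1.42 ± 0.23), PHO5 (-1.36 ± 0.26), TDH1 (-1.27 ± 0.22), TIR1 (-1.15 ± 0.21), RPL9B (-1.09 ± 0.21), WSC4 (-0.85 ± 0.16), RPS22B (-0.79 ± 0.14), the mitochondrial ADP/ATP carrier AAC3 (-0.77 ± 0.14) and EUG1, of the protein disulfide isomerase family (-0.70 ± 0.13), fell. RPL22B, not above background in its own deletion but higher in rpl22a, was lower. Ribosome biogenesis lay at 0.29 with 1 member higher (10 over the list alone, camera adjusted p = 2.70e-16, adjusted p = 0.155 with an estimated correlation). RNA polymerases I and III lay at 0.19 (0.000840), the proteasome at 0.20, or -0.02 without normalization and 0.11 relative to the median of all probe sets (5.74e-05), amino acid biosynthesis at 0.13, or -0.10 and 0.02 (0.00152), the induced stress response at -0.27 (0.000134), glycolysis and fermentation at -0.08 (0.00654), the pheromone response at -0.20 (0.000840) and small subunit ribosomal proteins at -0.05 (0.0313, or 0.0528 with shared probe sets added, a run chosen after seeing the data), each with adjusted p = 0.348 with an estimated correlation. The phosphate regulon lay at -0.26 with PHO5 lower (0.000350, adjusted p = 0.174 with an estimated correlation), the iron regulon at -0.14 (0.00960, adjusted p = 0.388 with an estimated correlation) and the a-specific genes at -0.14 (0.00544, adjusted p = 0.204 with an estimated correlation). The deleted genes and their paralogs, lower by design, lay at -0.68 (1.02e-10, adjusted p = 0.000416 with an estimated correlation). The split was 1 and 29 of 30 without normalization. The count was 59 with median centring, 74 with a floor at the 25th percentile, 13 with log2(value + 1), 89 with limma's trend and robust options and 86 with the replicate block. With the strain as the unit, which leaves out the spread of the wild type, it was 4013. It was 15, 21, 19, 18, 23, 24 or 66 without wild type replicate 1, rpl7a replicate 1, rpl7a replicate 2, rpl7b replicate 1, rpl7b replicate 2, rpl12b replicate 2 or rps0a replicate 1. A test for any difference among the 12 strains called 1057 of 9275 probe sets (11.4%).

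HXK1 (2.23 ± 0.42, adjusted p = 0.0178), GLK1 (1.52 ± 0.22, 0.00623), GLC3 (1.43 ± 0.30), DDR48 (1.41 ± 0.21) and GPP2, a glycerol-phosphate phosphatase (1.27 ± 0.21), were higher in the large than in the small subunit deletions. So were DPI8 (1.44 ± 0.25), VPS73 (1.23 ± 0.21), the ribosomal protein gene RPS9A (1.22 ± 0.18) and the vacuolar aminopeptidase APE1 (1.18 ± 0.21). CYB2, not above the background in 1 of the 4 small subunit strains, was also higher (adjusted p = 0.0202). Higher in the small subunit deletions were SNR52 (-2.61 ± 0.26, adjusted p = 0.00116) and SNR6 (-2.03 ± 0.24). The other 8 were not above the background in 1 to 6 of the 7 large subunit strains. They were at least 3.67-fold (YNCB0011C), 3.19-fold (the tRNA gene SUF17), 3.24-fold (YNCD0013C), 2.51-fold (YNCD0001W), 2.13-fold (YNCD0016C), 1.87-fold (YNCL0009C), 1.65-fold (YNCP0004C) and 1.53-fold (YNCC0001C) higher in the small subunit deletions. By class, 50 of 92 tRNA genes (median -1.05), 25 of 59 snoRNA genes (median -0.67) and 4 of 4 snRNA genes (median -1.23) were higher in the small subunit deletions. Of these, 34, 25 and 3 were above the background in most of the large subunit strains. Of 6319 protein-coding probe sets 91 were higher and 91 lower. The ratio of the 3' to the 5' probe sets of ACT1, a sign of RNA quality, averaged 2.04 in the small and 2.05 in the large subunit deletions.

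Induced stress response genes were higher in the large subunit deletions, 13 of 61 (25 over the list alone, median 0.45, camera adjusted p = 6.21e-14, adjusted p = 0.0997 with an estimated correlation). Of 27 citric acid cycle genes 4 were higher (median 0.18, 0.00236, adjusted p = 0.0997 with an estimated correlation; IDH2 0.70 ± 0.11, LSC2 0.63 ± 0.14). Of 40 oxidative phosphorylation genes 2 were (median 0.24, 3.21e-06, adjusted p = 0.282 with an estimated correlation; COX5B 1.06 ± 0.18), of the glycolysis and fermentation genes 3 (median 0.05, mean 0.33, 0.0123, adjusted p = 0.325 with an estimated correlation). Of the mitochondrial ribosomal proteins 3 were higher (median 0.20, 2.22e-06, adjusted p = 0.571 with an estimated correlation; MRPL31 0.91 ± 0.09), and of the heat shock factor chaperones 2 (median 0.16, 0.00478, adjusted p = 0.571 with an estimated correlation; HSP78 0.86 ± 0.20, HSP104 0.60 ± 0.11). The phosphate regulon, with GPP2, lay at 0.58 (0.0372, adjusted p = 0.824 with an estimated correlation) and amino acid biosynthesis at 0.12 (0.0115, adjusted p = 0.824 with an estimated correlation). Ribosome biogenesis genes were higher in the small subunit deletions, 21 of 129 (46 over the list alone, median -0.30, 3.19e-18, adjusted p = 0.357 with an estimated correlation), with DBP3 at -0.66 ± 0.09, RCL1 at -0.64 ± 0.14 and TSR1 at -0.62 ± 0.12. So were 2 of 27 genes of RNA polymerases I and III, RRN3 (-0.94 ± 0.15) and RPA190 (-0.46 ± 0.09; list median -0.22, 0.000208, adjusted p = 0.516 with an estimated correlation). Of 33 translation factors 3 were, GCD1 among them (-0.58 ± 0.12; list median -0.20, 1.26e-05, adjusted p = 0.103 with an estimated correlation). Large subunit ribosomal proteins, among them the deleted genes, lay at -0.10 (0.000184, adjusted p = 0.325 with an estimated correlation). With each strain as 1 unit, 308 probe sets differed, 101 higher and 207 lower in the large subunit deletions. The split was 70 and 92 of 162 without normalization and 106 and 130 of 236 with median centring. The count fell to 200, 190, 134, 116 or 186 without rpl12a, rps0a, rps0b, rps18a or rps18b.

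The log2 differences from wild type correlated at 0.736 for the rps18 pair and 0.639 for the rps0 pair, and at 0.422 for rpl12, 0.297 for rpl7 and 0.238 for rpl22. The mean over the 5 pairs was 0.466 against 0.409 over all pairings of the strains (exact permutation p = 0.133). Unlike paralogs, the pairings cross subunits, so the test cannot separate paralogy from subunit. Pairs of the same subunit correlated more than pairs across, by 0.102 on average (exact permutation p = 0.00909). The small subunit deletions had a mean of 0.690 (0.608 to 0.771), the large 0.394 (0.233 to 0.709, rpl12a with rpl22a) and pairs across subunits 0.358 (0.223 to 0.513). The rpl7, rpl22 and rps0 pairs lay below their subunit's mean, and rpl12 and rps18 above. All strains share the 2 wild-type arrays. Simulated strains with no shared change gave r = 0.501 and a covariance of 0.0562. The rpl7 (covariance 0.0494) and rpl22 (0.0403) pairs lay below both, with 0.0741 for rpl12, 0.154 for rps0 and 0.146 for rps18. A difference between small and large subunit pairs of paralogs was not tested. Mean covariances were 0.151 among small, 0.0766 among large and 0.0738 across subunits, and 0.0927 for the paralogs. With the wild-type arrays split between the members of a pair, the means were 0.406 among small, 0.116 among large and 0.108 across subunits, and 0.190 for the paralogs.

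**Figure D5:**
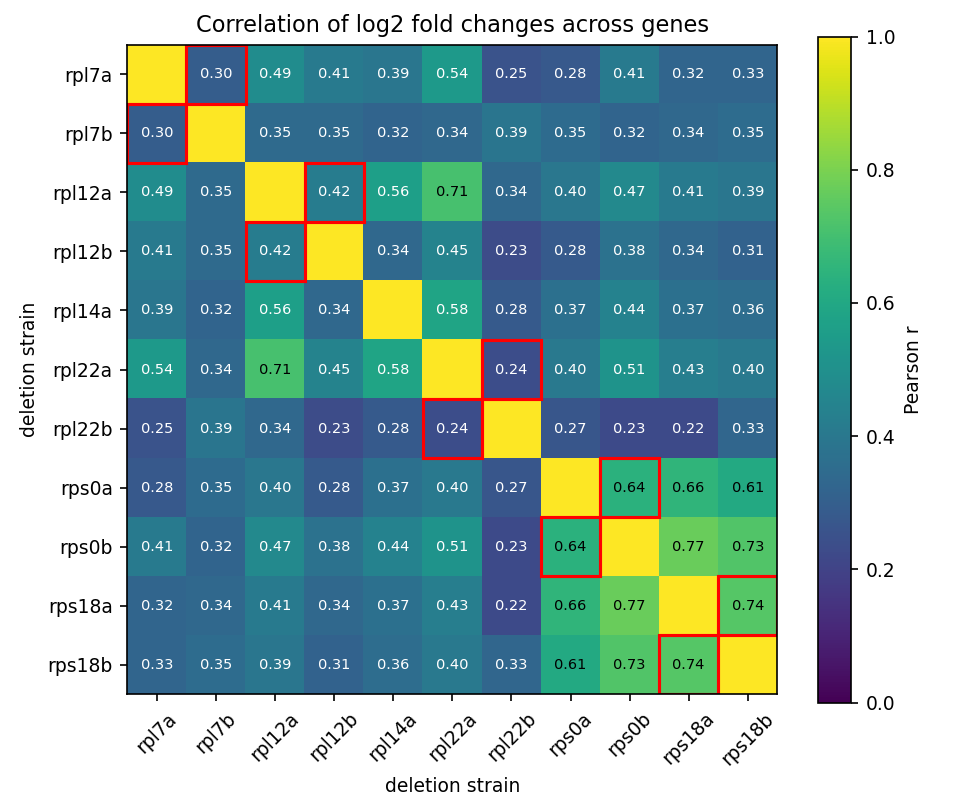
Correlation (r) of the log2 differences from wild type between each 2 of the 11 deletion strains over 5656 genes, with paralog pairs boxed in red. The 4 small subunit deletions form a block of higher values.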

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

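The test for alpha or diploid cells given among the other observations and the runs without chromosomes XVI, V and VIII were chosen after the result was seen, and the 3 tests of the chromosome pattern below were not. Chromosome XVI differed between the rpl7a and rpl7b deletions by 0.87 on average, and chromosome V between the rpl12a and rpl12b deletions by -0.82, a difference between the 2 deletions of a pair that its own test called in both cases. In rpl7a, rpl12b and rpl14a the genes of the chromosome with the remaining copy were higher than wild type. A few strongly raised genes do not account for this, since at least 94% of the chromosome's genes above background were higher in each strain, nor does a copied segment that spares an arm, since the lowest median of an arm was 0.66. The normalization between arrays does not account for it either, as the lowest excess over the other chromosomes was 0.83 without normalization. As a hypothesis, these 3 strains may carry an extra copy of the whole chromosome that holds the remaining copy, and it stays untested here because no DNA was measured.

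The phosphate regulon differed between the rpl7a and rpl7b deletions, at a median of -0.75 (camera adjusted p = 6.14e-06, adjusted p = 0.143 with an estimated correlation), with medians of -0.67 and 0.20 against wild type. No explanation of it was tested.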

How the results depend on the processing

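The runs without chromosomes XVI, V or VIII, on protein-coding genes alone, without rpl7a, rpl12b and rpl14a together, or with shared probe sets added were chosen after seeing the data. Of 529 values under alternative settings, 393 kept their direction and their side of the threshold or, for counts, lay within 1.5 times the count reported, and 136 did not. Unless a cause is named, the cause was not tested. The 7 deleted genes and the 3 chromosome shifts kept their number with each array left out, as did the 2 raised remaining copies, and the list calls ranged from 78 to 94 against wild type and from 26 to 38 between paralogs, large against small subunit deletions from 231 to 328, the test for any difference from 770 to 1381, the similarity of paralogs from 0.442 to 0.592 and the subunit difference from 0.0859 to 0.107. Of 158 values of named genes, 22 kept their call under all settings and 67 with each array left out, and 0 reversed.

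Without normalization the counts of changed probe sets were 367 (rpl7a), 16 (rpl12a), 10 (rpl12b), 90 (rpl14a), 82 (rpl22a), 16 (rps0a), 76 (rps0b), 202 (rps18a), 64 (rps18b), 155 (rpl7 pair), 24 (rpl12 pair), 74 (rpl22 pair), 0 (rps18 pair), 425 (any difference) and 162 (large against small), with 1 raised remaining copy and 136 list calls against wild type (29 higher and 107 lower, against 33 and 54 of 87 as reported). Between paralogs it gave 37 list calls, 12 higher and 25 lower, against 18 and 12 of 30. With median centring they were 123 (rpl12b), 186 (rpl14a), 68 (rps0a), 103 (rps18a), 91 (rpl12 pair), 159 (rpl22 pair), 0 (rps18 pair) and 59 (mean of the deletions), and the list calls 126 (28 and 98) and 40 (15 and 25). A floor at the 25th percentile gave 5 (rpl22b), 106 (rps18a) and 74 (mean), and log2(value + 1) gave 16 (rps0a), 135 (rps0b), 38 (rps18a), 4 (rps0 pair), 0 (rps18 pair) and 13 (mean). Without the dimmest 25% of probe sets the rps0 pair had 4 and the rps18 pair 0. The trend and robust options gave 44 (rpl12a), 127 (rps18a), 4 (rps0 pair), 0 (rps18 pair) and 89 (mean), and list tests were not run with the robust option, which camera does not offer. With only the 4 arrays compared, which leaves few degrees of freedom, 1 probe set was called in rpl7a, rpl12b, rpl14a, rpl22a, rps0a, rps0b, rps18a, rps18b, the rpl7 pair and the rpl12 pair, 2 in rpl12a and 0 in the rpl22, rps0 and rps18 pairs, where all arrays gave 1486, 784 and 446 at an unadjusted p under 0.05 in limma. Large against small subunit deletions gave 200, 190, 134, 116 or 186 without rpl12a, rps0a, rps0b, rps18a or rps18b, 145 on protein-coding genes alone (74 higher and 71 lower, fewer genes tested) and 201 without rpl7a, rpl12b and rpl14a. With an estimated correlation, 1 list call against wild type and 0 between paralogs were left. Without the genes of chromosomes XVI, V and VIII, 16 of the 87 list calls against wild type were lost and 7 appeared, and between paralogs 3 of 30 were lost and 6 appeared. With shared probe sets added, the small subunit list lost its call in the mean of the deletions (adjusted p = 0.0528). The large subunit list was then called lower in rpl7a (0.0383), rpl12b (0.0315) and the mean (0.0333) and higher in rps18a (0.0454), and the small subunit list lower in rpl7a (0.0462) and higher in the rps18 pair (0.0299). Their calls in rpl22b stayed (0.000105 and 0.00356). With the strain as the unit, which leaves out the spread of the wild type, the mean of the deletions gave 4013. Without the probe sets of chromosome XVI rpl7a had 300 (82 higher and 218 lower) and the rpl7 pair 214, without those of V rpl12b had 34 and the rpl12 pair 48, and without those of VIII rpl14a had 171 (69 higher and 102 lower).

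With 1 array left out, the lone array of its strain was assumed to vary like the other strains. The counts ranged from 232 to 330 (rpl7a), 4 to 13 (rpl7b), 17 to 26 (rpl12a), 54 to 168 (rpl12b), 99 to 169 (rpl14a), 97 to 248 (rpl22a), 6 to 27 (rpl22b), 11 to 459 (rps0a), 49 to 89 (rps0b), 21 to 53 (rps18a), 16 to 36 (rps18b), 15 to 66 (mean), 148 to 259 (rpl7 pair), 36 to 180 (rpl12 pair), 106 to 260 (rpl22 pair), 8 to 271 (rps0 pair) and 1 to 9 (rps18 pair). The highest values of rps0a, of its pair and of the mean came without rps0a replicate 1, whose partner, replicate 2, had the highest background of all arrays (30.8).

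With the replicate number as a block, the counts were 56 (rpl12a), 477 (rpl14a), 374 (rpl22a), 45 (rps0a), 418 (rps0b), 162 (rps18a), 48 (rps18b), 303 (rpl12 pair), 412 (rpl22 pair), 0 (rps18 pair) and 86 (mean). The sources do not say that arrays of the same number were handled together. In the 66 pairs of strains, residuals of arrays with the same number correlated at -0.0148 to 0.191, over 0.1 in 19. Hence 24 of 24 arrays matched their own number best, and the pairing was run as an alternative.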

Other observations

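The test for alpha or diploid cells below was chosen after the result was seen, and the others were not. In the small subunit deletions, probe sets of non-coding RNAs lay above wild type. The 92 tRNA probe sets had a median of 0.68 in rps0a, 0.77 in rps0b, 0.95 in rps18a and 1.13 in rps18b, with 0, 8, 4 and 4 called higher, against -0.17 to 0.26 in the large subunit deletions. The 59 snoRNA genes had medians of 0.44 to 0.61 and the 4 snRNA genes 1.34 to 1.98 in these 4 strains.

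More degraded RNA in the small subunit arrays would raise the ratio of the 3' to the 5' probe sets of ACT1, which averaged 2.04 in the small and 2.05 in the large subunit strains and 2.12 in wild type, with a difference of -0.01 and an SE of 0.0566 (exact permutation p = 0.576). The test leaves degradation open, since the spread of the large subunit strains, 1.84 to 2.24, would hide a small difference and non-coding RNAs are not read by this ratio. The normalization between arrays does not account for the pattern, as the median difference of the 155 non-coding probe sets was -0.84 without it and -0.88 with it. Labelling from an oligo-dT primer favours RNAs with a tail, so a change in tailing or in the share of non-coding RNA in the preparations may lie behind the pattern, and neither was measured.

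In rpl14a, a-specific and pheromone response genes were lower. Alpha or diploid cells mixed into the culture would lower all 7 a-specific genes alike, but their changes ranged over 3.36 (SE 0.73), and over 2.56 without ASG7, with STE6 at -0.48. MF(ALPHA)1, a gene of alpha cells, lay at 0.47 (adjusted p = 0.668). GPA1, on chromosome VIII, restrains the mating pathway. It differed by 0.20 ± 0.18, and an extra copy stays open without DNA data. As a hypothesis, signalling through the mating pathway may be lower in this strain, which no value here tests.

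Of 100 splits of 11 strains into 7 and 4, only the real one, large against small subunit, gave as many as 308 probe sets. The highest other split gave 37, with rpl7a, rpl12a, rpl14a and rpl22a as the 4. Chance is unlikely, but joint handling of the real 4 was not tested.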
